A study of Homo sapiens with 390 samples.

How the data were processed

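The series holds 390 arrays of the Affymetrix HG-U133 A type with 22283 probe sets, hybridised with RNA of human colon tissue, metastases, normal liver and lung, and cell lines. The table holds linear intensity values as deposited, 1 per probe set and array. The program that summarised probes to probe sets and the steps before deposition were not given in the sources used here. The 2% trimmed mean of each array lay between 150.03 and 150.06, so that the deposited intensity values had been scaled to a common mean. The upper quartile varied among arrays with an SD of 0.0433 on the log2 scale, and no further normalization was made.

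Values were raised to a floor of 16 and taken to log2, and 20.0% of values lay at or below the floor. Of the probe sets, 19071 carried 1 gene symbol, 1043 several and 2169 none. The 68 control probe sets and 31 probe sets of XIST, TSIX or Y chromosome genes were left out, which left 19034, and 19022 symbols were updated through their Entrez identifiers. Other genes of the X chromosome were kept. The probe set with the highest mean stood for a gene, giving 11939 genes. A gene at the floor on all arrays of a group gives a lower bound of the difference in group means where no array of the other group is at the floor. The number of arrays in the smaller group and the share of values at the floor limit the precision of the estimates.

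Groups followed the labels: 186 primary tumours (183 sources), 54 normal colon mucosa (53), 48 polyps (46), 47 liver metastases (39), 20 lung metastases (19), 13 normal livers (12), 7 normal lungs, 2 microadenomas and 7 colon cancer lines. Repeats of the line DLD-1 were averaged. Left out of the comparisons were 1 array of high grade dysplasia, being alone in its group, and the lines NCM460, MCF7 and LNCaP, which the labels do not call colon cancer.

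Differences were tested with limma 3.58.1 in R 4.3.3, with a linear model over all tissue groups, the source as a random block by duplicateCorrelation (statmod 1.5.0) and moderated variances with an intensity trend. The source correlation was 0.18 for tissue, 0.352 for the lines and 0.606 for polyps. In the alternative fit of microadenomas and mucosa alone this correlation could not be estimated and was set to 0. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts also required a 2-fold difference. Paired fits used the sources with arrays of both groups, with the source as a fixed term.

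Gene lists, 30 with 671 genes of which 579 were measured, were fixed before the files were opened and tested with cameraPR of limma at a preset correlation of 0.01 between genes and again at a correlation estimated from the data. Members were counted as risen or fallen by their adjusted p over all genes and, separately, over the list alone. Chromosomes were tested whole in the same way, since the reference held no arms. A host gene was at least 2-fold higher in normal liver or lung than in primary tumours with an adjusted p under 0.05, which gave 971 liver and 1096 lung genes.

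Genes for naming followed a rule fixed before the files were opened. Comparisons among mucosa, polyps, primary tumours, metastases and lines gave the 10 largest rises and the 10 largest falls that passed, and other comparisons 5 of each. Metastasis comparisons gave a further 10 of each that were not host genes. Each list gave the 4 members with the largest difference, whatever their p. XIST and Y chromosome genes were never named, and the text names a selection of the genes that the rule gave.

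Alternatives planned before the values were seen were no source block, 1 array per source and group, only the 2 groups in the fit, paired fits, no variance trend, quantile normalization, log2 of the value plus 16, leaving out the dimmest 40% of probe sets, the median over the probe sets of a gene, an estimated list correlation, host genes left out, host list means as covariates, and leaving out each microadenoma or the line WiDr. Chosen after seeing the data were covariates for the 5'/3' ratios of actin and GAPDH or for the CreX spike-in signal, and leaving out 30 arrays with an actin 5'/3' log2 ratio under -1.5, colon arrays with hepatocyte transcripts, 1 primary tumour array with a liver profile, the 2 outlying normal lung arrays, HT29 or SW620.

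The fits were tested on simulated data with the sources and group sizes of the real arrays. Changes were placed only in genes with a mean well above the floor, so recovery of dim genes was not tested. The simulated source correlation was 0.2 for every fit, lower than that found for the lines and polyps. With a log2 change of 1, all genes were recovered for primary tumours against mucosa, 94% for lung metastases against primary tumours, 78% for the lines and 44% for microadenomas against mucosa. Unchanged genes made up 1.27 to 7.56% of the calls. Tables were handled with the data.table package, version 1.17.8, and figures drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.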

Results

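The series holds expression profiles of colorectal tumours along their course, from normal colonic mucosa through polyps and primary tumours to metastases of the liver and lung, with normal liver, normal lung and cell lines beside them. All differences are log2 differences of intensity given with the standard error of the limma fit, and a positive value means higher in the group named first. Arrays of a group came from separate sources according to the labels, apart from the repeats and shared sources counted here.

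Primary tumours had lost the transcripts of the mature colonic surface and gained those of Wnt signalling when compared with normal mucosa, and single genes of matrix, proteases and chemokines rose. Of 11939 genes, 690 differed at least 2-fold, 235 higher and 455 lower in tumours (186 tumour and 54 mucosa arrays). The largest fall was in ZG16, a lectin of goblet cell mucus (-5.92 ± 0.24), which was lower in the tumour in 44 of the 44 sources that gave both tissues. GUCA2B (-4.81 ± 0.11) and GUCA2A (-4.51 ± 0.14), the peptide ligands of the colonic guanylate cyclase receptor, fell. So did CLCA4 (-5.56 ± 0.18) and the ion and water transporters SLC26A3 (-4.33 ± 0.29) and AQP8 (-4.50 ± 0.18). The carbonic anhydrases CA1 (-4.73 ± 0.17) and CA2 (-4.54 ± 0.21) and the membrane protein MS4A12 (-4.43 ± 0.19) fell by similar amounts. The largest rise was in COL11A1, a fibrillar collagen (3.94 ± 0.20, higher in 41 of the 44 sources), followed by CDH3, the placental cadherin (3.74 ± 0.15), and INHBA, an activin subunit (3.20 ± 0.17). The neutrophil chemokines CXCL8 (3.13 ± 0.21), CXCL3 (2.67 ± 0.16) and CXCL1 (2.22 ± 0.14) rose, as did CEMIP, which depolymerises hyaluronan (2.89 ± 0.15), and the keratin KRT23 (2.71 ± 0.26).

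The gene lists, fixed before the data were examined, followed the same division. Of 30 absorptive colonocyte genes measured, 29 fell and 1 did not pass, with a median of -2.46 (camera adjusted p = 6.24e-58). Among 14 goblet cell genes 12 fell (median -1.27, adjusted p = 1.15e-09), including the mucus proteins FCGBP (-4.21 ± 0.31), CLCA1 (-4.19 ± 0.25) and MUC2 (-2.80 ± 0.28). The hormone transcripts CHGA (-3.78 ± 0.16), GCG (-3.72 ± 0.12) and PYY (-3.20 ± 0.10) led the enteroendocrine list, in which 15 of 16 genes fell (adjusted p = 3.69e-18). Smooth muscle genes fell in 17 of 17 cases (median -1.95, adjusted p = 1.21e-16), with DES at -3.19 ± 0.26 and MYH11 at -3.12 ± 0.25. Enteric glia and neuron genes fell in 12 of 14 (adjusted p = 2.09e-14), with the neuropeptide VIP at -2.36 ± 0.10 and the glial cadherin CDH19 at -2.36 ± 0.09. The mean level of the smooth muscle list varied widely among mucosa arrays (9.77 ± 1.45, SD) and was 7.78 ± 1.07 in tumours. All 8 metallothioneins fell (median -1.89, adjusted p = 8.71e-10), MT1M by the most (-3.58 ± 0.18). Lists of mast cells (9 of 11 fell, adjusted p = 9.12e-06, KIT -1.47 ± 0.12), adipocytes (8 of 11 fell, adjusted p = 0.000225, CFD -2.90 ± 0.17) and red blood cells (3 of 7 fell, adjusted p = 0.00605, HBB -2.04 ± 0.16) were also lower. The median of the red blood cell list was near 0, so that call rested on a few genes. Among them was CA1, which also belongs to the absorptive colonocyte list, so the call is not specific to red blood cells.

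Rising lists included Wnt target genes, of which 17 of 19 rose and 2 fell (median 0.82, adjusted p = 1.59e-07). They included the stem cell receptor LGR5 (2.39 ± 0.22), its partner ligase RNF43 (1.72 ± 0.12) and the transcription factor SOX9 (1.55 ± 0.09). Ribosome biogenesis genes rose in 17 of 19 cases (median 0.68, adjusted p = 2.24e-10, RRP9 1.31 ± 0.10). All 36 cell cycle genes rose (median 0.86, adjusted p = 7.56e-16), and the list had adjusted p = 0.0731 with an estimated correlation. Among them were the spindle factor TPX2 (1.40 ± 0.10) and the ubiquitin enzyme UBE2C (1.33 ± 0.09). Fibroblast and matrix genes (25 of 27 rose and 1 fell, median 1.21, adjusted p = 1.52e-13), led after COL11A1 by the stromal protease FAP (2.60 ± 0.17), had adjusted p = 0.108 with an estimated correlation. Matrix metalloproteinases (10 of 12 rose and 1 fell, adjusted p = 0.000785) included MMP1 (2.72 ± 0.26), MMP7 (2.66 ± 0.20) and MMP11 (2.61 ± 0.14) and had adjusted p = 0.0731 with an estimated correlation. Inflammatory chemokines and cytokines (14 of 22 rose and 2 fell, adjusted p = 0.000556) had adjusted p = 0.111 with an estimated correlation. Oxidative phosphorylation genes fell in 31 of 33 (median -0.36, adjusted p = 8.71e-10, UQCRC1 -0.70 ± 0.07, SDHD -0.65 ± 0.06), with adjusted p = 0.077 with an estimated correlation. B and plasma cell genes fell in 15 of 18 with 2 rises (adjusted p = 6.59e-06, JCHAIN -2.72 ± 0.24) and had 0.108 with an estimated correlation. Immediate early genes fell in 14 of 24 with 4 rises (adjusted p = 0.0164, KLF4 -2.03 ± 0.13) and had 0.51 with an estimated correlation. Adjusted over the list alone, 13 goblet, 26 fibroblast, 32 oxidative phosphorylation, 16 B and plasma cell and 15 immediate early genes moved in the main direction, and the counts of the other lists named were equal.

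The remaining 12 lists did not pass in this comparison (adjusted p from 0.0781 to 0.982): class II antigen presentation, T and NK, myeloid, endothelial, mesenchymal transition, interferon, hypoxia and glycolysis, epithelial junction and keratin, Paneth, hepatocyte, lung epithelium and ciliated airway genes. Single members still moved, such as VEGFA of the hypoxia list (1.19 ± 0.09), the matrix protein TGFBI (1.96 ± 0.11), the T cell protease GZMB (1.30 ± 0.16), and the interferon targets CXCL10 (1.01 ± 0.15) and IFIT1 (-1.66 ± 0.21). By chromosome, the median difference was 0.24 for chromosome 20, 0.15 for 13, 0.12 for 7 and -0.06 for 18, against 0.03 for all genes. Their adjusted p values were 4.19e-05, 0.00631, 0.0279 and 0.00631, and each had adjusted p = 0.887 with an estimated correlation. Hepatocyte transcripts were present on 8 mucosa and 4 tumour arrays, and 699 genes differed without those arrays.

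**Figure D1:**
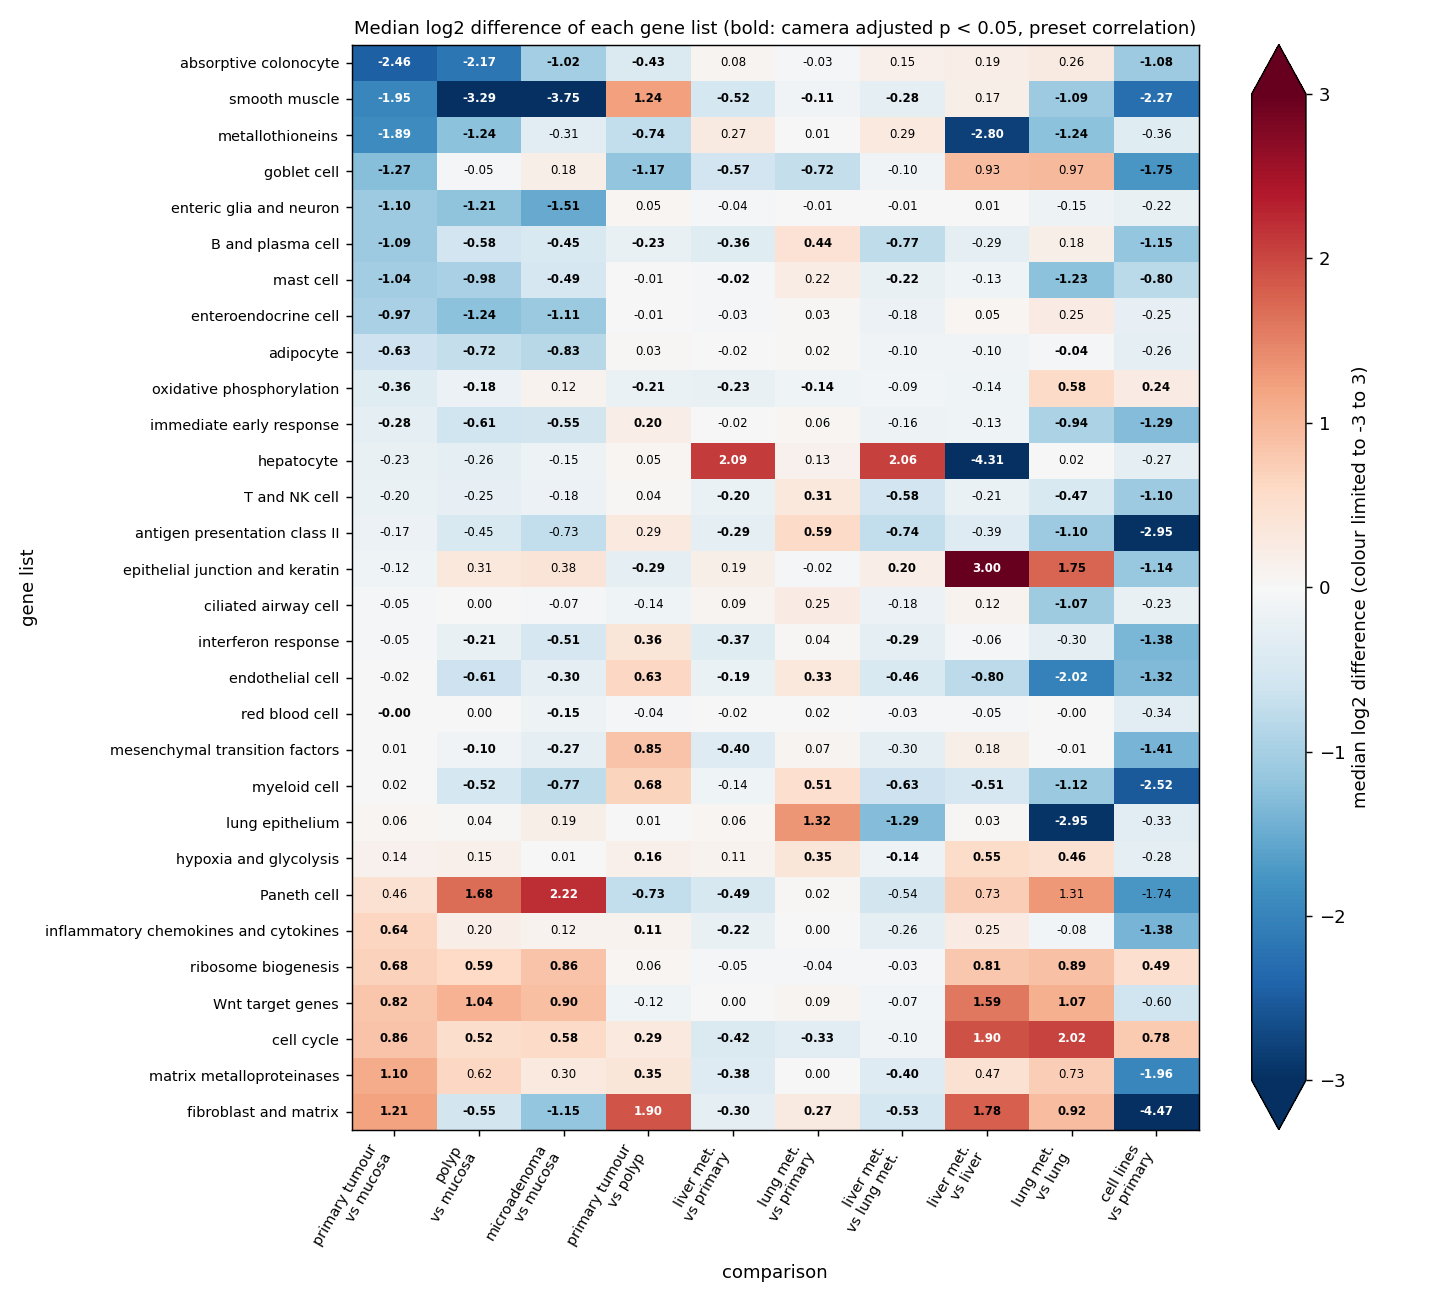
Median log2 difference of the genes of each of 30 lists (vertical axis) in 10 comparisons (horizontal axis), with bold type for a camera adjusted p under 0.05 at the preset correlation. The absorptive colonocyte list had a median of -2.46 in primary tumours and -2.17 in polyps, and the fibroblast and matrix list 1.21 and -0.55.

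Polyps shared the loss of surface cell transcripts and the Wnt rise of tumours but lacked their gain of matrix. In all, 741 genes differed at least 2-fold from normal mucosa, 170 higher and 571 lower (48 and 54 arrays, 7 shared sources). CDH3 (3.58 ± 0.19) and CEMIP (3.38 ± 0.19) rose in 7 of the 7 sources with both tissues. The epithelial defence genes DUOX2, an oxidase (3.54 ± 0.31), and LCN2, an iron-binding protein (3.48 ± 0.27), rose with the calcium-binding S100P (3.11 ± 0.23). CXCL3 (2.69 ± 0.20) and CCL20, a chemokine of the epithelium (2.53 ± 0.34), were higher too. Wnt target genes rose in 14 of 19 cases with no falls (median 1.04, adjusted p = 6.08e-10), with MMP7 at 2.78 ± 0.27, LGR5 at 2.60 ± 0.29, RNF43 at 2.08 ± 0.16 and SOX9 at 1.83 ± 0.12. Absorptive colonocyte genes fell in 29 of 30 cases with 1 rise (median -2.17, adjusted p = 1.07e-41), led by CLCA4 (-4.92 ± 0.24), GUCA2B (-4.76 ± 0.14), GUCA2A (-4.47 ± 0.18), AQP8 (-4.40 ± 0.24) and CA1 (-4.29 ± 0.22).

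Muscle and nerve transcripts were also lower in polyps. Smooth muscle genes fell in 17 of 17 cases (median -3.29, adjusted p = 1.6e-39), with the actin-bound LMOD1 at -4.62 ± 0.27, DES at -4.61 ± 0.34, CNN1 at -4.54 ± 0.28 and MYH11 at -4.36 ± 0.33. Enteric glia and neuron genes fell in 12 of 14 (adjusted p = 5.5e-19, VIP -2.71 ± 0.14, CDH19 -2.51 ± 0.12). Enteroendocrine genes fell in 14 of 16 (adjusted p = 1.72e-19, GCG -3.52 ± 0.16, CHGA -3.42 ± 0.22, PYY -3.10 ± 0.13). Ribosome biogenesis genes rose in 17 of 19 (median 0.59, adjusted p = 1.56e-08, RRP9 1.06 ± 0.14), while mast cell genes fell in 9 of 11 with 1 rise (adjusted p = 3.36e-05). Cell cycle genes rose in 34 of 36 (median 0.52, adjusted p = 1.15e-06, NEK2 1.00 ± 0.15) and had adjusted p = 0.365 with an estimated correlation. Fibroblast and matrix genes fell in 16 of 27 with 3 rises (median -0.55, adjusted p = 0.000331), with adjusted p = 0.514 with an estimated correlation. Fibronectin FN1 (-2.23 ± 0.20) and the proteoglycan DCN (-2.12 ± 0.17) were among them. Endothelial genes (14 of 19 fell, adjusted p = 1.5e-06, CLDN5 -2.25 ± 0.16) and myeloid genes (16 of 23 fell, adjusted p = 0.000331, MRC1 -1.41 ± 0.18) had adjusted p = 0.161 and 0.462 with an estimated correlation. Paneth cell genes rose in 8 of 10 (median 1.68, adjusted p = 0.00459), including the defensin DEFA6 (2.11 ± 0.41) and the lectin REG3A (1.81 ± 0.35), with adjusted p = 0.189 with an estimated correlation. The mean of the goblet list did not differ (3 rose and 1 fell, adjusted p = 0.51). In it ZG16 fell (-4.61 ± 0.31) while SPINK4 (1.55 ± 0.35) and the trefoil factor TFF3 (0.70 ± 0.24) rose. Metallothioneins (7 of 8 fell, adjusted p = 0.000125, MT1M -2.28 ± 0.24) had adjusted p = 0.208 with an estimated correlation. Interferon genes (13 of 28 fell and 3 rose, adjusted p = 0.0165, IFIT1 -2.63 ± 0.28) had adjusted p = 0.576 with an estimated correlation. Mesenchymal transition factors (6 of 13 fell and 1 rose, adjusted p = 0.0132, VIM -1.43 ± 0.15) had adjusted p = 0.365 with an estimated correlation. With adjustment over the list alone, 35 cell cycle, 18 fibroblast and 15 endothelial genes moved in the main direction, and the counts of the other lists named were equal.

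In the paired fit of the 7 shared sources 657 genes differed at least 2-fold. There DUOX2 (2.33), CXCL3 (1.40), LGR5 (2.35), CCL20 (2.16), REG3A (1.60), NEK2 (0.89), TFF3 (0.10), FN1 (-2.46) and the defensin DEFA6 no longer passed, and SPINK4 reversed to -0.46 without passing. The Paneth list had a paired median of 1.17 (adjusted p = 0.221), the goblet list -0.51 (adjusted p = 0.0453) and the class II list -0.49 (adjusted p = 0.0197).

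Tumours and polyps were both compared with the same mucosa arrays. They shared 93 of their 235 and 170 higher genes and 308 of their 455 and 571 lower genes, and 1 gene moved in opposite directions. Independent lists of those sizes would share 3.35 and 21.8 genes. Groups simulated without an effect, with simulated mucosa arrays in common, shared 0 in 20 simulations. Hardly any gene can pass without an effect, so that 0 does not show what the shared mucosa contributes. With the mucosa arrays split between both comparisons, 88 higher and 309 lower genes were shared. The covariance of the differences over genes was 0.231 (0.225 with split mucosa), against 0.00578 in simulations without an effect. Their correlation over genes was 0.7906, against 0.6043 in those simulations, so a shared mucosa group alone gives a high correlation.

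The 2 microadenomas, very small adenomas, were compared with the same mucosa arrays as polyps, which can give part of a likeness. They shared some changes with polyps and differed from them in others, and the overlap of calls was not counted. Against mucosa, 407 genes differed at least 2-fold (113 higher and 294 lower), but this number rested on few arrays: it was 23 without microadenoma replicate 1 and 282 without replicate 2. The defensin DEFA6 (5.71 ± 1.48), DUOX2 (4.41 ± 1.11), LCN2 (3.74 ± 0.98) and CEMIP (3.51 ± 0.70) rose the most among named genes. The muscle genes MYH11 (-5.50 ± 1.19), CNN1 (-5.44 ± 1.00), MYL9 (-5.26 ± 0.87) and LMOD1 (-4.69 ± 0.99) fell with complement C3 (-4.71 ± 1.04). The 2 microadenoma arrays lay far apart for MYH11 and MYL9 (SD 2.88 and 2.35). CNN1, MYL9, LMOD1 and C3 were each at the floor on 50% of microadenoma arrays. Smooth muscle genes fell in 15 of 17 cases (limma camera adjusted p = 2.64e-27), enteric glia and neuron genes in 7 of 14 (adjusted p = 2.17e-13) and enteroendocrine genes in 6 of 16 (adjusted p = 5.05e-10). VIP and SCGN, a calcium sensor of endocrine cells, were at the floor on both microadenoma arrays and differed by -3.10 ± 0.49 and -2.55 ± 0.36, values that depend on the floor. CDH19 (-2.41 ± 0.43) and GCG (-2.77 ± 0.59) fell with them. Each was at the floor on 50% of microadenoma arrays, as was GUCA2B of the absorptive colonocyte list. Ribosome biogenesis genes rose in 6 of 19 cases (adjusted p = 1.27e-09, NIP7 1.91 ± 0.43, NOLC1 1.06 ± 0.32) and Wnt target genes in 3 of 19 (adjusted p = 0.000102, SLC12A2 1.86 ± 0.46). LGR5 (3.13 ± 1.06) did not pass (adjusted p = 0.0632 in limma), but it passed when only the 2 groups were fitted (2.94), when dim probe sets were left out (3.17) and with the median over probe sets (2.95).

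Absorptive colonocyte genes fell in 5 of 30 cases in microadenomas (AQP8 -3.63 ± 0.87, CA1 -3.12 ± 0.80, GUCA2B -2.81 ± 0.50; limma camera adjusted p = 2.44e-08), with adjusted p = 0.0769 with an estimated correlation. Fibroblast and matrix genes (6 of 27 fell, FN1 -3.94 ± 0.72 and DCN -3.03 ± 0.63, adjusted p = 1.03e-09) had adjusted p = 0.327 with an estimated correlation. Paneth genes (1 of 10 rose, median 2.22, adjusted p = 0.00214) had adjusted p = 0.148 with an estimated correlation. No cell cycle gene passed, although the list median was 0.58 (limma camera adjusted p = 1.53e-05) with adjusted p = 0.466 with an estimated correlation. Adjusted over the list alone, 17 smooth muscle, 10 glia and neuron, 8 enteroendocrine, 13 ribosome biogenesis, 6 Wnt, 8 colonocyte and 12 fibroblast genes moved in the main direction. A direct test of microadenomas against polyps found 21 genes different at least 2-fold. In it the absorptive colonocyte list was higher in microadenomas (median 0.83, limma camera adjusted p = 5.47e-10), the fibroblast list lower (-0.64, adjusted p = 1.39e-05) and the oxidative phosphorylation list higher (0.29, adjusted p = 0.000163). These lists had adjusted p = 0.197, 0.916 and 0.916 with an estimated correlation. Without microadenoma replicate 1, VIP, CDH19 and SCGN still passed and the 18 other named genes that had passed did not, and without replicate 2 DEFA6, DUOX2, LCN2, SLC12A2 and CA1 did not. AQP8 and GUCA2B no longer passed when only the 2 groups were fitted, nor NOLC1 without the source block.

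Primary tumours differed from polyps above all by their stroma. Here 273 genes differed at least 2-fold, 189 higher and 84 lower in tumours (186 and 48 arrays). COL11A1 (3.11 ± 0.21), FN1 (2.74 ± 0.16), the matrix proteins THBS2 (2.48 ± 0.16) and POSTN (2.12 ± 0.17), COL1A1 (2.48 ± 0.16), INHBA (2.35 ± 0.18) and FAP (2.34 ± 0.18) rose. So did SPP1, a secreted phosphoprotein of macrophages and tumour cells (2.72 ± 0.22). All 27 fibroblast and matrix genes were higher (median 1.90, adjusted p = 8.3e-78), and THBS2 was higher in 9 of 10 shared sources. In the other direction, all 14 goblet cell genes were lower (median -1.17, adjusted p = 1.02e-18), with CLCA1 at -3.84 ± 0.27, FCGBP at -3.72 ± 0.33, SPINK4 at -2.99 ± 0.29 and the mucins MUC2 and MUC4 at -2.75 ± 0.30 and -2.57 ± 0.25. DUOX2 (-2.83 ± 0.25) and the immunoglobulin receptor PIGR (-2.07 ± 0.21) were lower too. Mesenchymal transition factors rose in 10 of 13 cases (median 0.85, adjusted p = 1.69e-10), with TNC at 1.97 ± 0.22, VIM at 1.18 ± 0.13 and SNAI2 at 1.11 ± 0.13.

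Several other lists of that comparison passed only at the preset correlation. Smooth muscle genes (15 of 17 rose, adjusted p = 1.84e-13, MYL9 2.15 ± 0.20, TAGLN 1.93 ± 0.18, CALD1 1.52 ± 0.13) had adjusted p = 0.114 with an estimated correlation. Endothelial genes (18 of 19 rose, adjusted p = 3.1e-11, ENG 0.80 ± 0.10) had adjusted p = 0.0516 with an estimated correlation. Myeloid genes (21 of 23 rose, adjusted p = 2.68e-09, CD163 1.02 ± 0.19, CD14 0.88 ± 0.16) had adjusted p = 0.245 with an estimated correlation. Matrix metalloproteinases (6 of 12 rose and 1 fell, adjusted p = 0.000491, MMP11 1.61 ± 0.15, MMP2 1.52 ± 0.15) had adjusted p = 0.114 with an estimated correlation. Cell cycle genes (26 of 36 rose, median 0.29, adjusted p = 6.26e-07, TPX2 0.62 ± 0.11, UBE2C 0.58 ± 0.10) and interferon genes (17 of 28 rose, adjusted p = 0.000491, CXCL10 1.00 ± 0.17) had adjusted p = 0.373 and 0.42 with an estimated correlation. Lower lists were oxidative phosphorylation (21 of 33, adjusted p = 3.77e-07, SDHA -0.45 ± 0.08), absorptive colonocytes (18 of 30 with 2 rises, adjusted p = 0.000109, ADH1C -1.56 ± 0.22) and epithelial junction and keratin (12 of 23, adjusted p = 0.000491, GPA33 -1.17 ± 0.15), which had adjusted p = 0.253, 0.279 and 0.373 with an estimated correlation. Also lower were metallothioneins (7 of 8, adjusted p = 0.000491, MT1M -1.30 ± 0.20) and Paneth cells (6 of 10, adjusted p = 0.00244, DEFA6 -1.81 ± 0.34, DEFA5 -1.79 ± 0.27), with adjusted p = 0.299 and 0.191 with an estimated correlation. Hypoxia genes rose in 11 of 22 and fell in 2 (adjusted p = 0.0203, LOX 1.61 ± 0.14), with adjusted p = 0.373 with an estimated correlation. With p adjusted over the list alone, 29 cell cycle, 7 metalloproteinase, 19 interferon, 26 oxidative phosphorylation and 7 Paneth genes moved in the main direction, and the counts of the other lists named were equal.

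The comparison of tumours with polyps within sources rested on few arrays. In a paired fit of the 10 shared sources, 0 genes differed at least 2-fold in limma and 1563 had an unadjusted p under 0.05. FN1 (1.56), THBS2 (1.43) and CLCA1 kept their direction there without passing, and the fibroblast (1.16) and goblet (-0.83) lists still passed at the preset correlation. The paired fit lost the cell cycle (median 0.13), Paneth (-0.17) and hypoxia (0.09) lists. The B and plasma cell list, lower in the fit of all arrays (7 of 18 fell and 1 rose, median -0.23, adjusted p = 0.034, JCHAIN -1.98 ± 0.26, adjusted p = 0.493 with an estimated correlation), reversed to 0.07 in the paired fit. By chromosome, medians were higher for 20 (0.14, adjusted p = 1.16e-06) and 13 (0.09, adjusted p = 0.0043) and lower for 14 (-0.08, adjusted p = 0.0043) and 18 (-0.11, adjusted p = 0.00634), each with adjusted p = 0.883 with an estimated correlation.

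Polyps could be divided by the disease label of their source, into 36 from sources labelled colon cancer and 12 from sources labelled colon polyp. No gene differed at least 2-fold at the threshold in limma, and 859 had an unadjusted p under 0.05. PLA2G2A, a phospholipase (1.31 ± 0.61, adjusted p = 0.668), and JCHAIN (-0.86 ± 0.44, adjusted p = 0.699) differed without passing. The fibroblast and matrix list had a higher median in polyps of sources labelled colon cancer (0.45, adjusted p = 5.68e-07), with adjusted p = 0.697 with an estimated correlation. In simulated data with these groups 84% of genes with a log2 change of 1 were recovered. Those genes lay well above the floor, and the simulated source correlation was 0.2, against 0.606 in the polyps.

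**Figure D2:**
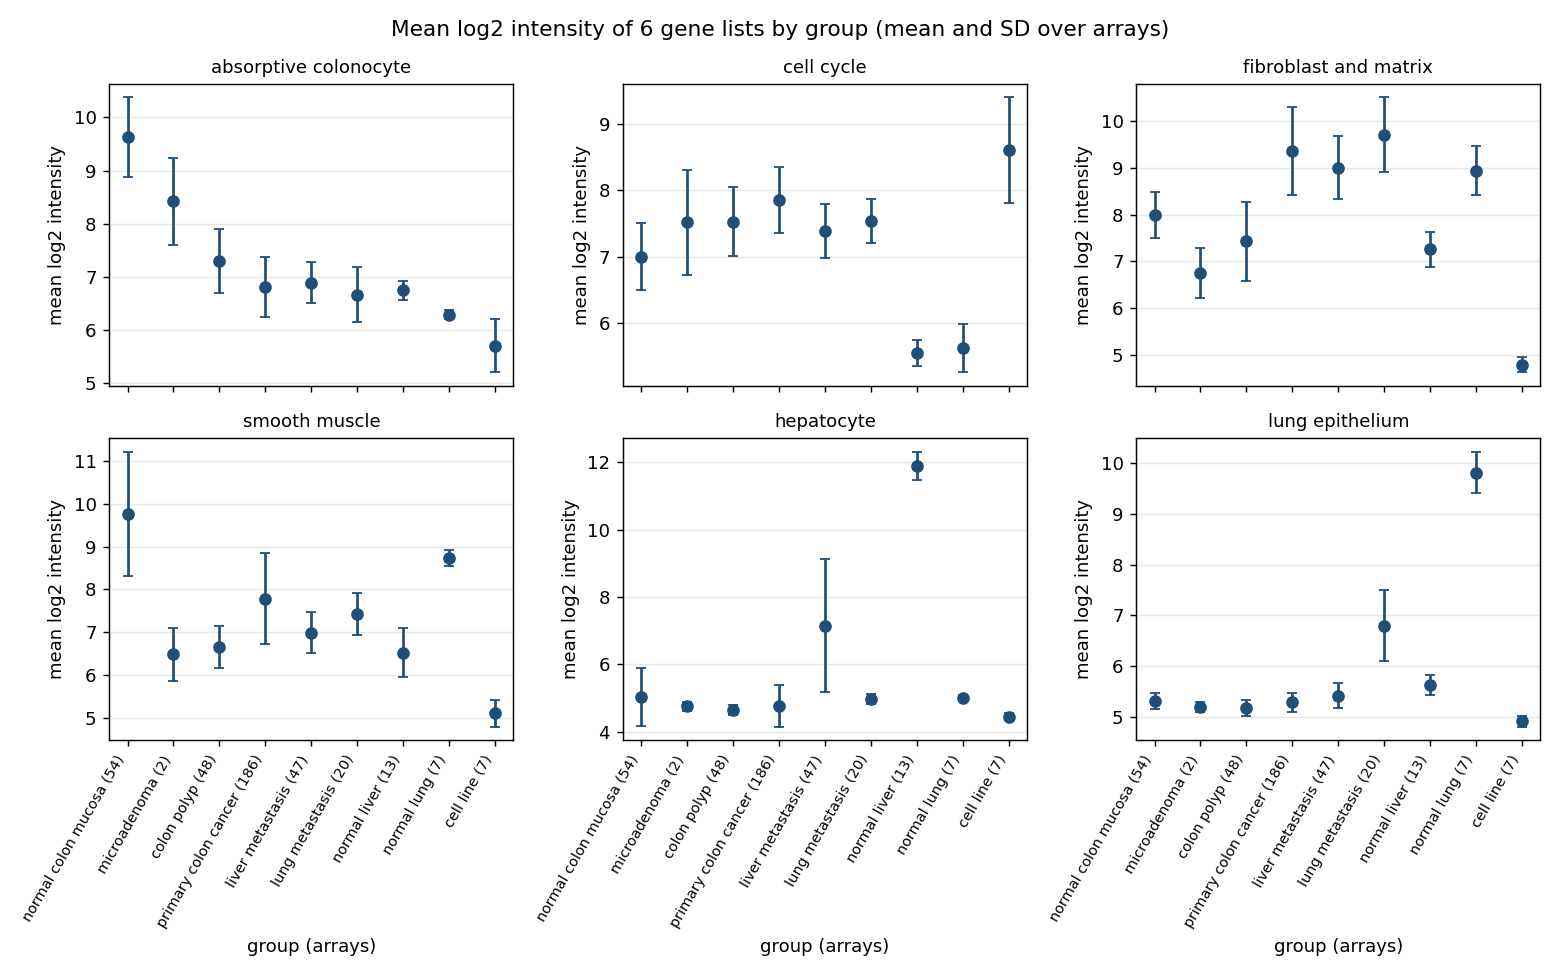
Mean log2 intensity (vertical axes) of the genes of 6 lists in 9 groups (horizontal axis, number of arrays in brackets), with points for the mean and bars for the SD over arrays. The hepatocyte list was at 7.14 ± 1.97 in liver metastases and 11.9 ± 0.418 in normal liver, and the fibroblast list at 9.36 ± 0.944 in primary tumours and 7.43 ± 0.846 in polyps.

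Liver metastases differed from primary tumours by a gain of liver transcripts, and single stromal, muscle and mucus genes were lower. The fibroblast, smooth muscle and goblet lists were lower only at the preset correlation (adjusted p = 0.624, 0.396 and 0.396 with an estimated correlation). At least 2-fold changes were found in 167 genes, 94 higher and 73 lower (47 and 186 arrays, 5 shared sources), and in 109 without the dimmest 40% of probe sets. Most rises were genes of the liver itself, such as ALB, serum albumin (4.62 ± 0.25), HP, haptoglobin (4.41 ± 0.21), the fibrinogen chain FGB (4.29 ± 0.20) and ORM1, an acute phase protein (4.15 ± 0.24). In all, 32 of 33 hepatocyte genes rose (median 2.09, adjusted p = 7.8e-118). Outside the genes that were at least 2-fold higher in normal liver than in primary tumours, 75 genes differed, 4 higher and 71 lower. Leaving out genes high in liver removes mainly rises, so this imbalance is largely built in. Those lower included the interstitial collagenase MMP1 (-3.17 ± 0.29), the stromelysin MMP3 (-2.76 ± 0.20), MMP2 (-1.98 ± 0.15), the muscle genes ACTG2 (-2.24 ± 0.21) and DES (-1.96 ± 0.29), the matrix protein FBLN1 (-1.97 ± 0.16), the signal protein WNT5A (-1.90 ± 0.14) and MLIP (-1.98 ± 0.34). Mucus genes were lower as well, with MUC2 at -1.79 ± 0.32 and SPINK4 at -1.66 ± 0.30, and so were the endothelial VWF (-2.42 ± 0.14) and the plasma cell gene JCHAIN (-2.17 ± 0.27). Among the rises named, CYP1B1, a cytochrome (1.36 ± 0.15), SPP1 (1.46 ± 0.23) and the proteoglycan BGN (0.86 ± 0.15) were higher in 5 of 5 shared sources. VEGFA (0.90 ± 0.10), KRT23 (1.03 ± 0.29) and the lipase CEL (1.13 ± 0.27) were higher over all arrays.

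Matrix metalloproteinases fell in 9 of 12 cases with 1 rise (median -0.38, adjusted p = 1.53e-08), and this list and the hepatocyte list were the ones of that comparison that also passed with an estimated correlation. Cell cycle genes were lower (28 of 36, median -0.42, adjusted p = 1.07e-15), with RRM2, a ribonucleotide reductase, at -0.86 ± 0.12 and the cyclin CCNB1 at -0.79 ± 0.12, and had adjusted p = 0.232 with an estimated correlation. Oxidative phosphorylation genes (25 of 33 fell, adjusted p = 7.24e-11, ATP5F1B -0.55 ± 0.07) had adjusted p = 0.229 with an estimated correlation, and smooth muscle genes (12 of 17 fell, adjusted p = 1.65e-07) had 0.396. B and plasma cell genes (11 of 18 fell, adjusted p = 4.23e-06) and interferon genes (17 of 28 fell, adjusted p = 1.41e-05, IDO1 -0.85 ± 0.14) had adjusted p = 0.269 and 0.428 with an estimated correlation. Goblet genes (9 of 14 fell, adjusted p = 0.000427) had adjusted p = 0.396 with an estimated correlation. Fibroblast and matrix genes (14 of 27 fell and 4 rose, adjusted p = 0.000601, COL11A1 -1.16 ± 0.22), T and NK genes (13 of 28 fell, adjusted p = 0.0017) and class II genes (6 of 12 fell, adjusted p = 0.0168, HLA-DRA -0.99 ± 0.20) had adjusted p = 0.624, 0.495 and 0.495 with an estimated correlation. Chemokines (10 of 22 fell and 4 rose, adjusted p = 0.0196, CXCL5 -1.43 ± 0.23, CXCL1 -1.10 ± 0.16) and mast cell genes (5 of 11 fell, adjusted p = 0.0196, CPA3 -1.26 ± 0.17) had 0.428. Within lists, adjusted over the list alone, 33 hepatocyte, 29 cell cycle, 26 oxidative phosphorylation and 15 smooth muscle genes moved in the main direction, and 1 mast cell gene rose. Chromosome 13 had a median of 0.18 (adjusted p = 0.000427), with adjusted p = 0.743 with an estimated correlation.

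Within the 5 sources that gave both a primary tumour and a liver metastasis, 0 genes differed at least 2-fold in limma and 553 had an unadjusted p under 0.05. In that paired fit the medians of the cell cycle (0.15), class II (0.58), fibroblast (0.28), interferon (0.35), T and NK (0.16), myeloid (0.69) and mesenchymal transition (0.14) lists and of chromosome 13 (-0.05) were reversed, and the metalloproteinase list (-0.10) no longer passed. At the preset correlation the class II (camera adjusted p = 1.33e-19), myeloid (2.7e-19), fibroblast (1.015e-05), interferon (1.015e-05) and T and NK (0.0277) lists passed in the reversed direction. Named genes that reversed there were MLIP (1.72), RRM2 (0.32), CCNB1 (0.26), ATP5F1B (0.09), HLA-DRA (0.92), IDO1 (0.74) and CEL (-1.23). Liver metastases also had a lower actin 5'/3' log2 ratio than primary tumours (-1.17 ± 0.783 and -0.573 ± 0.405, SD), a sign of degraded RNA. With those ratios as covariates 139 genes differed, and HLA-DRA, CEL and the lists of class II, fibroblast, chemokine, Paneth and mesenchymal transition genes no longer passed. With the hepatocyte and lung epithelium list means as covariates 135 genes differed, 63 of them among the 167. COL11A1 and the fibroblast, goblet and Paneth lists no longer passed, and the median of the metallothionein list (-0.77) reversed, as did that of the hepatocyte list (-0.16), itself a covariate.

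Lung metastases carried lung epithelial transcripts and a small set of other changes relative to primary tumours. Of 87 genes that differed at least 2-fold, 67 were higher and 20 lower (20 and 186 arrays, no shared sources). Of these, 35 were not genes of normal lung (15 higher and 20 lower), a filter that removes mainly rises. The surfactant proteins SFTPC (4.44 ± 0.16), SFTPD (2.70 ± 0.09) and SFTPB (2.10 ± 0.14), the airway secretory gene SCGB1A1 (3.08 ± 0.17) and the phosphate transporter SLC34A2 (2.75 ± 0.14) rose. In the lung epithelium list, 19 of 20 genes were higher (median 1.32, adjusted p = 1.33e-84). Rises outside normal lung genes included CYP1B1 (1.72 ± 0.22), SPP1 (1.40 ± 0.33), BGN (1.39 ± 0.21), MLIP (1.47 ± 0.48) and the immunoglobulin chain IGLC1 (1.53 ± 0.36). MMP3 (-2.37 ± 0.28), the developmental gene MAB21L2 (-2.08 ± 0.25), SPINK4 (-1.81 ± 0.43), DES (-1.73 ± 0.41), MUC2 (-1.72 ± 0.45), PLA2G2A (-1.62 ± 0.42), the chemokine CXCL14 (-1.62 ± 0.34), ACTG2 (-1.34 ± 0.30) and ADAMDEC1 (-1.17 ± 0.27) were lower. So was BAX, a regulator of cell death (-1.49 ± 0.20).

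Apart from the lung epithelium list, each list call of that comparison was lost with an estimated correlation. Cell cycle genes (12 of 36 fell, median -0.33, adjusted p = 1.42e-08, RRM2 -0.75 ± 0.17, CCNA2 -0.55 ± 0.16), myeloid genes (11 of 23 rose, adjusted p = 4.97e-05, LILRB1 0.96 ± 0.23) and goblet genes (5 of 14 fell, adjusted p = 0.00113) had adjusted p = 0.626 with an estimated correlation. Hypoxia genes rose in 11 of 22 (adjusted p = 0.000166, BNIP3 1.20 ± 0.29, NDRG1 0.80 ± 0.16), with adjusted p = 0.427 with an estimated correlation. B and plasma cell genes (7 of 18 rose, adjusted p = 0.00346, IGHM 1.96 ± 0.36, MZB1 1.26 ± 0.34), class II genes (8 of 12 rose, adjusted p = 0.0107, HLA-DRA 0.78 ± 0.28, CD74 0.77 ± 0.20) and endothelial genes (6 of 19 rose, adjusted p = 0.00346, CLDN5 1.18 ± 0.20) had adjusted p = 0.626 with an estimated correlation. Fibroblast genes (7 of 27 rose, adjusted p = 0.0246, TIMP1 0.73 ± 0.15) had 0.958 and T and NK genes (9 of 28 rose, adjusted p = 0.00347) 0.731. Metalloproteinases as a list did not differ (2 rose and 2 fell, adjusted p = 0.632), with MMP9 at 0.82 ± 0.22 and MMP1 at -1.09 ± 0.41, and the chemokine CCL18 of the macrophages rose by 1.57 ± 0.32. Adjusted over the list alone, 18 cell cycle, 15 myeloid, 7 goblet, 12 hypoxia and 10 B and plasma cell genes moved in the main direction, and the counts of the other lists named were equal.

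These calls changed to differing degrees with covariates for host tissue, 5'/3' ratios and spike-in signal. With the hepatocyte and lung epithelium list means as covariates 124 genes differed, only 11 of them among the 87. The medians of the cell cycle (0.22), class II (-0.08), endothelial (-0.54), fibroblast (-0.56) and T and NK (-0.12) lists, and the genes RRM2 (0.22), CCNA2 (0.36) and CLDN5 (-0.58), then reversed. Among the other named genes, 23 of 31 no longer passed, which alone does not show that their differences went away. CLDN5, SFTPB and SLC34A2 belong to the lung epithelium list, so their changes were partly built into the fit. Lung metastasis arrays had a lower actin 5'/3' log2 ratio than primary tumour arrays (-1.13 ± 0.741 and -0.573 ± 0.405, SD), as liver metastases had. With the 5'/3' ratios as covariates 99 genes differed, 75 of them among the 87, and MMP1 (-0.71) and the smooth muscle list (-0.16) no longer passed. The arrays also had a higher CreX spike-in signal than primary tumour arrays (13.4 ± 0.522 and 12.2 ± 0.475, log2, SD). With that signal as a covariate 97 genes differed, 62 of them among the 87, and SPINK4 (-1.35), MUC2 (-1.22), PLA2G2A (-1.26), ADAMDEC1 (-0.51), RRM2 (-0.43), CCNA2 (-0.28) and MMP1 (-0.29) no longer passed.

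Both sites of metastasis were compared with the same primary tumours, and both had lower 5'/3' ratios than these. They shared 11 of their 94 and 67 higher genes and 14 of their 73 and 20 lower genes, and 11 genes moved in opposite directions. Independent lists would share 0.527 and 0.122 genes, and with the primary arrays split between both comparisons 11 higher and 11 lower genes were shared. Groups simulated without an effect shared 0 in 20 simulations. Hardly any gene can pass there, so that 0 does not show what the shared primaries contribute. The covariance of the differences was 0.0311 (0.028 with split primaries) against 0.00165 in simulations. Their correlation over genes was 0.3235, against 0.138 in the simulations. Outside host genes, 12 genes were lower at both sites, ACTG2, ADAMDEC1, CDCA8, CXCL14, CXCL5, DES, GSR, MAB21L2, MMP1, MMP3, MUC2 and SPINK4, and CYP1B1 and SPP1 were higher.

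**Figure D3:**
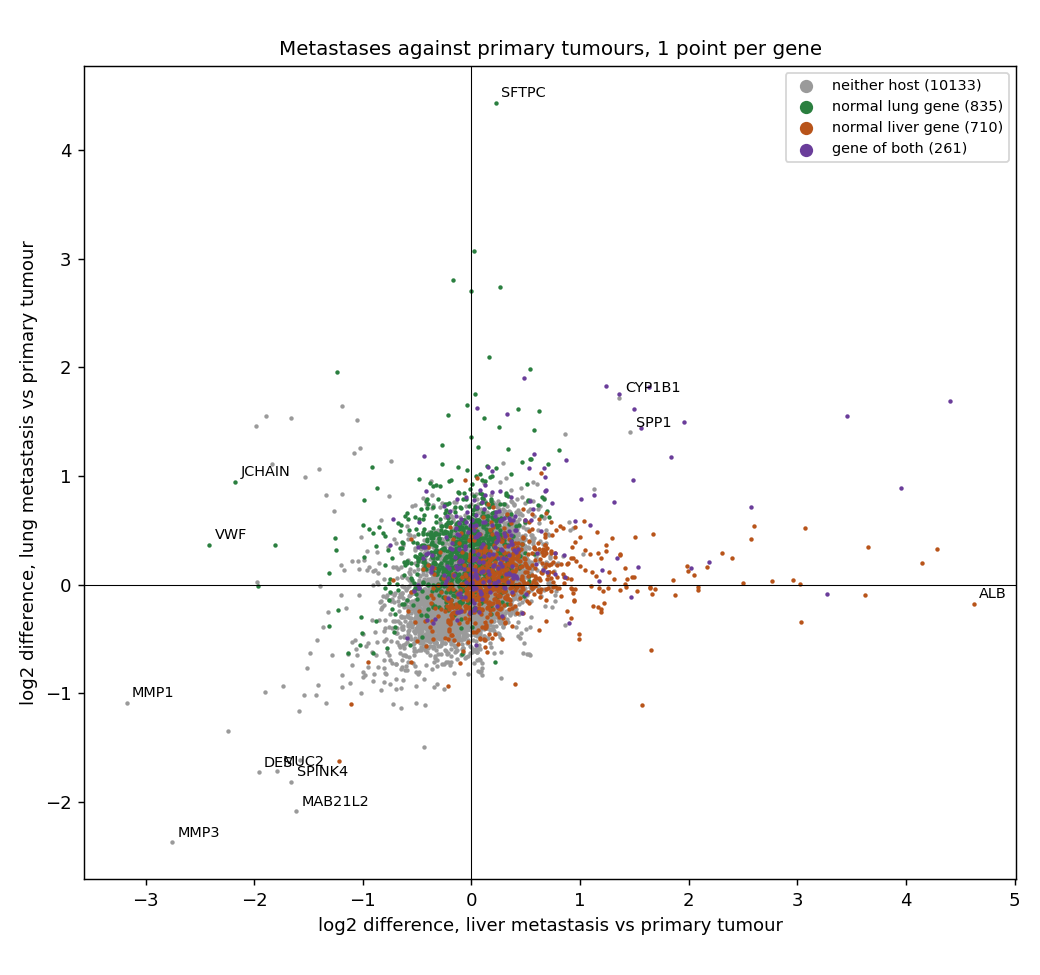
Log2 difference of each gene in liver metastases (horizontal axis) and lung metastases (vertical axis) against primary tumours, with 1 point per gene coloured by whether the gene was at least 2-fold higher in normal liver or lung than in primary tumours. MMP3 was lower at both sites (-2.76 and -2.37), while ALB was higher in liver metastases (4.62) and SFTPC in lung metastases (4.44).

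Compared directly, liver and lung metastases differed in host tissue transcripts, in B and plasma cell genes and in single vascular genes such as VWF. Their arrays also differed in CreX spike-in signal (12.5 ± 0.589 and 13.4 ± 0.522, log2, SD), so array processing may add to these differences. There were 209 genes at least 2-fold different, 83 higher and 126 lower in liver metastases (47 and 20 arrays; 131 genes without the dimmest 40% of probe sets), and 56 of them were genes of neither normal host tissue (7 higher and 49 lower). ALB (4.80 ± 0.40) and FGB (3.96 ± 0.33) were higher in liver metastases, SFTPC (-4.21 ± 0.19) and SCGB1A1 (-3.05 ± 0.19) in lung metastases. Hepatocyte genes (31 of 33 higher, adjusted p = 2.62e-80) and lung epithelium genes (14 of 20 lower, adjusted p = 2.73e-66) parted accordingly. B and plasma cell genes were lower in liver metastases (10 of 18, median -0.77, adjusted p = 1.09e-12), with the immunoglobulin genes IGLC1 at -3.19 ± 0.41 and IGKC at -2.95 ± 0.40. JCHAIN was at -3.12 ± 0.43, MZB1 at -2.29 ± 0.38 and the B cell coactivator POU2AF1 at -2.29 ± 0.30. Endothelial genes were lower as well (10 of 19, adjusted p = 8.99e-11), with VWF at -2.78 ± 0.23, CLDN5 at -1.62 ± 0.23 and PECAM1 at -1.08 ± 0.17. So were metalloproteinases (6 of 12, adjusted p = 2.85e-05), with MMP1 at -2.09 ± 0.47, MMP2 at -2.00 ± 0.25 and MMP12 at -1.38 ± 0.32. MLIP was lower by the most among non-host genes (-3.45 ± 0.55). Of the few higher, the insulin signal adaptor IRS2 (1.17 ± 0.21), C2CD2L (1.19 ± 0.17) and the keratin KRT20 (1.15 ± 0.37) reached 2-fold, and RNF43 rose by 0.71 ± 0.23. KRT20 and RNF43 no longer passed with 1 array per source.

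Class II genes (9 of 12 lower, adjusted p = 1.35e-06, HLA-DRA -1.77 ± 0.32, CD74 -1.19 ± 0.23) had adjusted p = 0.12 with an estimated correlation. T and NK genes (12 of 28 lower, adjusted p = 7.23e-09, CD2 -1.05 ± 0.18, CD3D -0.98 ± 0.19) and myeloid genes (11 of 23 lower, adjusted p = 8.53e-08, S100A9 -1.26 ± 0.24) had adjusted p = 0.149 and 0.32 with an estimated correlation. Fibroblast genes (8 of 27 lower, adjusted p = 6.6e-08, LUM -1.46 ± 0.27) and mast cell genes (5 of 11 lower, adjusted p = 0.000268, CPA3 -1.69 ± 0.27) had adjusted p = 0.425 and 0.117 with an estimated correlation. With adjustment over the list alone, 15 lung epithelium, 12 B and plasma cell, 13 endothelial, 7 metalloproteinase, 21 T and NK, 18 myeloid and 13 fibroblast genes were lower. With both host list means as covariates 182 genes differed, 28 of them among the 209. The medians of the fibroblast (0.39), smooth muscle (0.79) and mast cell (0.09) lists reversed, and the endothelial and metalloproteinase lists no longer passed. The hepatocyte and lung epithelium lists were themselves covariates, and CLDN5 belongs to the lung epithelium list. MZB1 (-1.62), POU2AF1 (-1.70), HLA-DRA (-1.80), CD74 (-0.97), CD2 (-0.80), CD3D (-0.81), MMP1 (-1.24), MMP12 (-1.40) and S100A9 (-0.97) did not pass either in that fit. Nor did CLDN5 (-0.35), PECAM1 (-0.18), MMP2 (-0.82), IRS2 (0.48), RNF43 (0.21), CPA3 (-0.52) and LUM (-0.61), and a lost call alone does not show that a difference went away. Chromosome 13 had a median of 0.14 (adjusted p = 0.000186), with adjusted p = 0.947 with an estimated correlation.

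Against their host tissues, metastases carried the epithelial transcripts of colon tumours. In the liver, 2339 genes differed at least 2-fold, 1341 higher and 998 lower in metastases (47 and 13 arrays, 9 shared sources). The epithelial keratin KRT19 (5.95 ± 0.27), the intestinal cadherin CDH17 (5.77 ± 0.29), the adhesion gene FERMT1 (5.75 ± 0.28), CEACAM5, the carcinoembryonic antigen (5.32 ± 0.28), and EPCAM (5.27 ± 0.20) were higher in 9 of 9 shared sources. Enzymes and plasma proteins of the liver fell, with MAT1A at -6.17 ± 0.26, AGXT at -6.10 ± 0.26, HPD at -5.85 ± 0.23, SERPINC1 at -5.80 ± 0.29, PLG at -5.72 ± 0.27 and TTR at -5.70 ± 0.34. All 33 hepatocyte genes were lower (median -4.31, adjusted p = 6.07e-37). Epithelial junction and keratin genes rose in 21 of 23 cases (median 3.00, adjusted p = 2.53e-18). Cell cycle genes rose in 35 of 36 (median 1.90, adjusted p = 4.67e-15, TOP2A 3.71 ± 0.20, NEK2 3.04 ± 0.24) and had adjusted p = 0.268 with an estimated correlation. Wnt target genes rose in 14 of 19 with 1 fall (adjusted p = 0.00236, LGR5 3.77 ± 0.46, SOX9 3.16 ± 0.19) and had adjusted p = 0.0941 with an estimated correlation. Ribosome biogenesis (18 of 19 rose, adjusted p = 0.000642, RRP9 1.73 ± 0.21), fibroblast (22 of 27 rose and 1 fell, adjusted p = 0.000131, COL1A1 3.61 ± 0.30) and metallothionein genes (8 of 8 fell, adjusted p = 2.21e-05, MT1M -4.71 ± 0.38) had adjusted p = 0.336, 0.868 and 0.278 with an estimated correlation. Endothelial genes (11 of 19 fell and 1 rose, adjusted p = 0.00796, KDR -2.12 ± 0.18) and myeloid genes (13 of 23 fell, adjusted p = 0.0258, CD14 -3.26 ± 0.30) had 0.771 and 0.926. In the paired fit of 9 sources the myeloid list no longer passed (median -0.11), although those of metalloproteinases (0.63) and Paneth cells (0.95) did. Adjusted over the list alone, 23 fibroblast genes rose and 1 myeloid gene rose, and the other counts were equal.

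In the lung, 1570 genes differed at least 2-fold, 697 higher and 873 lower in metastases (20 and 7 arrays, with 7 shared sources). FABP1, a fatty acid carrier of the gut (4.99 ± 0.79), CDH17 (4.78 ± 0.39), the trypsin inhibitor SPINK1 (4.46 ± 0.59), the lectin LGALS4 (4.35 ± 0.34) and CEACAM5 (4.10 ± 0.38) were higher in 7 of 7 shared sources. CYP4B1 (-5.07 ± 0.20), TMEM100 (-4.99 ± 0.23), TNNC1 (-4.63 ± 0.22), FABP4 (-4.56 ± 0.42) and the alveolar receptor AGER (-4.50 ± 0.19) were lower in 7 of 7. Lung epithelium genes fell in 19 of 20 cases (limma camera adjusted p = 3.45e-54, SCGB1A1 -4.46 ± 0.30, SFTPD -4.44 ± 0.15), endothelial genes in 18 of 19 with 1 rise (adjusted p = 2.26e-22, TIE1 -3.62 ± 0.33, CDH5 -3.07 ± 0.27). Ciliated airway genes fell in 9 of 10 (adjusted p = 4.53e-06, TPPP3 -3.50 ± 0.37). All 36 cell cycle genes rose (adjusted p = 1.35e-28, TOP2A 3.11 ± 0.28), as did 20 of 23 epithelial junction genes with 1 fall (adjusted p = 1.02e-15). Higher too were 17 of 19 ribosome biogenesis genes (adjusted p = 2.42e-08, RRP9 1.89 ± 0.29) and 11 of 19 Wnt target genes with 1 fall (adjusted p = 0.000852, LGR5 3.11 ± 0.63, SOX9 2.56 ± 0.26). Oxidative phosphorylation (21 of 33 rose, adjusted p = 2.28e-06, COX5A 1.13 ± 0.17), myeloid (18 of 23 fell, adjusted p = 2.02e-05, MRC1 -2.28 ± 0.38) and fibroblast genes (13 of 27 rose and 1 fell, adjusted p = 0.0205, COL1A1 2.27 ± 0.41) had adjusted p = 0.257, 0.387 and 0.661 with an estimated correlation. With p adjusted over the list alone, 21 epithelial, 21 myeloid and 14 fibroblast genes moved in the main direction, and the counts of the other lists named were equal. Without 2 normal lung arrays that lay apart in list means, 1637 genes differed.

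The cell lines had lower stromal and class II transcripts than the tumours. Against 186 primary tumours, the 7 colon cancer lines differed at least 2-fold in 1560 genes, 287 higher and 1273 lower. The median of all genes was -0.10, and with quantile normalization it was 0.02 and 29.5% of the changed genes were higher instead of 18.4%. The collagens COL1A1 and COL3A1 were lower by the most. COL1A1, SPARC, IGLC1 and VWF were at the floor in all 7 lines and in no tumour, so their differences of -7.71, -6.75, -7.23 and -3.84 were at least that large. OLFM4 (-5.07 ± 0.99) was at the floor in all 7 lines and in 8.60% of tumours. COL3A1 was at -7.70 ± 0.30 with 6 of 7 lines at the floor. All 27 fibroblast and matrix genes were lower (median -4.47, adjusted p = 8.06e-65), as were 11 of 12 class II genes (median -2.95, adjusted p = 1.15e-18), with CD74 at -5.73 ± 0.35 and HLA-DRA at -5.63 ± 0.46. Of the metalloproteinases 9 of 12 were lower (adjusted p = 2.08e-06, MMP12 -4.95 ± 0.44). Among rises were the secreted factors BMP4 (3.12 ± 0.61) and DKK1 (2.95 ± 0.46), the serine enzyme PSAT1 (2.76 ± 0.37), the RNA-binding IGF2BP3 (2.74 ± 0.50), the elongation factor EEF1A2 (2.68 ± 0.26) and the glutamine carrier SLC1A5 (2.24 ± 0.22).

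Other lists of the line comparison passed only at the preset correlation. Cell cycle genes (26 of 36 rose, median 0.78, limma camera adjusted p = 6.22e-09, CDC6 1.85 ± 0.23, CCNB1 1.32 ± 0.28) had adjusted p = 0.248 with an estimated correlation. Ribosome biogenesis genes (11 of 19 rose and 1 fell, adjusted p = 0.000101, NIP7 1.71 ± 0.27) had adjusted p = 0.158 with an estimated correlation. Myeloid (22 of 23 fell, adjusted p = 5.39e-16, LAPTM5 -4.04 ± 0.27, C1QA -3.84 ± 0.37), smooth muscle (16 of 17 fell, adjusted p = 1.76e-10, TAGLN -5.05 ± 0.46) and endothelial genes (15 of 19 fell, adjusted p = 3.05e-09) had adjusted p = 0.106, 0.146 and 0.122 with an estimated correlation. Interferon (21 of 28 fell, adjusted p = 4.09e-08, IFI27 -4.23 ± 0.39, GBP1 -3.89 ± 0.34), immediate early (20 of 24 fell and 1 rose, adjusted p = 1.75e-08, FOS -3.68 ± 0.47) and chemokine genes (14 of 22 fell, adjusted p = 6.61e-05, CXCL8 -3.01 ± 0.58) had adjusted p = 0.216, 0.106 and 0.137 with an estimated correlation. Mesenchymal transition genes (9 of 13 fell, adjusted p = 1.53e-05, VIM -3.41 ± 0.37) had 0.137. Epithelial junction and keratin genes were lower (15 of 23 fell and 4 rose, adjusted p = 0.00135, CEACAM5 -4.72 ± 0.41, CDH17 -3.27 ± 0.46), with adjusted p = 0.307 with an estimated correlation. Adjusted over the list alone, 10 metalloproteinase, 27 cell cycle, 12 ribosome biogenesis, 17 smooth muscle, 16 endothelial and 22 immediate early genes moved in the main direction, and 5 epithelial genes rose. The arrays labelled HT29 and SW620 resembled each other as closely as repeats of 1 line, and 1489 and 1554 genes differed when either was left out.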

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

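The spike-in signals and the setting without 2 normal lung arrays were chosen after the result was seen, and Dixon's test for an outlying array and the interaction test before their results were seen.

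In normal lung, the array with the highest list mean lay apart from the 6 others for 7 lists: cell cycle (6.392, nearest 5.696), epithelial junction and keratin (8.427, nearest 7.766), fibroblast and matrix (10.08, nearest 9.02), hypoxia and glycolysis (8.55, nearest 8.289), interferon response (8.494, nearest 7.984), matrix metalloproteinases (7.749, nearest 6.169) and Wnt target genes (7.663, nearest 6.784). Dixon's test was applied to 60 groups of 7 values and marks about 1 in 20 groups by chance. The 7 values came from 2 arrays, 1 of which gave 6 of them. Without these arrays 1637 genes differed between lung metastases and normal lung instead of 1570, and the metallothionein list no longer passed (median -0.90).

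The interaction test, of metastasis minus host tissue in liver against the same in lung, passed for 2195 genes at 2-fold or more. It also holds the difference between normal liver and normal lung. A gene that differs between these organs can therefore pass it without any difference between the metastases. The medians of the test, liver minus lung, were -4.515 for the hepatocyte list (limma camera adjusted p = 3.17e-34, 0.0211 with an estimated correlation), 3.398 for the lung epithelium list (1.67e-26 and 7.99e-11) and 1.16 for the ciliated airway list (0.0021 and 0.0192). Only at the preset correlation did the oxidative phosphorylation (-0.717), endothelial (1.156), smooth muscle (1.562), metallothionein (-1.373) and epithelial junction (0.7642) lists pass.

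Spike-in signals, which no comparison used as a measurement, differed on lung metastasis arrays: CreX was at 13.44 and BioB at 8.701 on the log2 scale, against 12.21 and 6.54 on primary tumour arrays.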

How the results depend on the processing

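Covariates for 5'/3' ratios and CreX and leaving out arrays of low 5'/3' ratio, colon arrays with hepatocyte transcripts or a liver profile, 2 normal lung arrays or the lines HT29 and SW620 were chosen after the result was seen, and all other settings before. Of the counts of genes changed at least 2-fold under alternative settings, 134 stayed within 1.5 times the reported count and 8 did not. This compares totals and not which genes were called. With host tissue covariates the totals stayed, but most of the genes called were others. The polyps divided by disease label, with 0 genes, also count as having stayed. Quantile normalization kept the direction and call of all 313 results of genes named in the text and of 318 list results. Another 7 list results newly passed and 5 no longer did. Of the 1421 results of genes given by the naming rule, 1384 stayed the same, 23 were weaker and 14 stronger. Without arrays of low actin 5'/3' ratio, HLA-DRA and CEL in liver metastases against primary tumours and KRT20 and RNF43 in liver against lung metastases no longer passed. In lung metastases against primary tumours, MMP1 no longer passed with log2 of the value plus 16 or only the 2 groups in the fit, nor HLA-DRA with the median over probe sets. KRT20 in liver against lung metastases no longer passed with only the 2 groups. An estimated correlation ended 123 list calls and 10 chromosome calls. Signal near the floor limits the dimmest genes: without the dimmest 40% of probe sets, 109 genes differed between liver metastases and primary tumours and 131 between liver and lung metastases, with fewer genes tested. With host genes left out, 75 genes differed between liver metastases and primary tumours, 35 between lung metastases and primary tumours and 56 between both sites, by construction. Microadenomas differed from mucosa in 23 to 282 genes in leave-one-out fits, in which the lone array is assumed to vary like the other groups.

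The paired fit gave 0 genes for primary tumours against polyps and 0 for liver metastases against primary tumours, with fewer arrays. In it 441 of the 770 results of genes given by the naming rule stayed the same, 275 were weaker and 53 reversed, 39 of these in liver metastases against primary tumours, 7 in primary tumours against polyps, 4 in polyps against mucosa and 3 in liver metastases against normal liver. Of genes named in the text, 122 results stayed the same, 70 were weaker and 8 reversed. Reversed were SPINK4 in polyps against mucosa (-0.46), the B and plasma cell list in primary tumours against polyps (0.0723) and, in liver metastases against primary tumours, MLIP (1.72), RRM2 (0.32), CCNB1 (0.26), ATP5F1B (0.0914), HLA-DRA (0.92), IDO1 (0.74), CEL (-1.23), chromosome 13 (-0.0481) and the lists of absorptive colonocytes (-0.50), class II (0.58), cell cycle (0.15), fibroblast and matrix (0.28), interferon (0.35), mesenchymal transition (0.14), myeloid (0.69) and T and NK cells (0.16). The B and plasma cell (-0.16) and Paneth (-0.24) lists kept a median below 0 but turned direction in camera. The absorptive colonocyte, class II, fibroblast, interferon, myeloid and T and NK lists passed in the reversed direction at the preset correlation. The cause was not tested.

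With host tissue covariates 208 of the 411 results of genes given by the rule stayed the same, 147 were weaker and 48 reversed, 31 of these in lung metastases against primary tumours. Of genes named in the text, 49 results stayed the same, 40 were weaker and 3 reversed. Reversed in liver metastases against primary tumours were the hepatocyte (-0.16) and metallothionein (-0.77) lists. Reversed in lung metastases against primary tumours were RRM2 (0.22), CCNA2 (0.36), CLDN5 (-0.58) and the lists of adipocytes (-0.43), class II (-0.0806), cell cycle (0.22), endothelial cells (-0.54), epithelial junction and keratin (0.17), fibroblast and matrix (-0.56), mast cells (-0.38), oxidative phosphorylation (0.21), ribosome biogenesis (0.15), T and NK cells (-0.12) and Wnt target genes (0.42). Reversed between liver and lung metastases were the fibroblast (0.39), hepatocyte (-0.043), mast cell (0.0907) and smooth muscle (0.79) lists. The hepatocyte and lung epithelium lists are themselves covariates in these fits, so changes of these lists and their members, CLDN5 among them, are partly built in, and for the other lists and genes the cause was not tested.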

Other observations

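Tests of hepatocyte transcripts on colon arrays, of the lines HT29 and SW620 and of the CreX signal were chosen after the result was seen, and the other tests of lower genes in liver metastases once those falls were known but before the tests were run. The redrawn splits were planned before the result was seen.

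Lines outside the comparisons carried markers of their tissues. ESR1 and TFF1 were at 10.40 and 12.28 (log2) in MCF7 and KLK3 at 12.26 in LNCaP. NCM460 had KRT20 at 11.42 and LGALS4 at 11.50, near the levels in WiDr (10.97 and 11.85), while DLD-1 had KRT20 at the floor.

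Outside host genes, 71 genes were lower in liver metastases than in primary tumours, with a median of -1.287. Dilution by liver tissue was weighed with host list means as covariates, which left a median of -1.317. Of the 71 genes, 64 were then lower by adjusted p alone and 51 also by at least 2-fold. RNA quality was weighed with 5'/3' covariates, which left -1.123, with 69 genes lower by adjusted p and 46 also 2-fold. Less muscle wall was weighed with the smooth muscle list mean as a covariate, which left -1.196 for 67 genes. Of these, 66 were lower by adjusted p and 42 also 2-fold. Array processing was weighed with the CreX spike-in signal as a covariate, which left -1.264, with 71 genes lower by adjusted p and 63 also 2-fold. With each of these 4 covariates fitted by itself, the median fall stayed above 2-fold. The genes had been chosen as lower on the same arrays, and no joint fit was made. A covariate may also follow its cause only in part, so these fits exclude none of the 4 causes. Processing that the CreX signal does not follow, sampling and a difference of the tumour tissue were not tested and stay open. In the paired fit of 5 sources the median was -0.611 and no gene passed in limma, so the falls are not established within sources.

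Hepatocyte transcripts appeared on 8 mucosa and 4 primary tumour arrays. Over the 33 hepatocyte genes, the excess on mucosa arrays ranked like the level in normal liver (rank correlation 0.8048, genes not being independent replicates), which is in line with liver RNA on those arrays. With arrays averaged within sources, the 7 mucosa sources that also gave a liver array had a higher list mean than the 46 others (5.982 ± 1.496 and 4.867 ± 0.589, SD; permutation p = 0.00343), in line with liver tissue of the same source on part of the arrays. The highest list mean among the other sources was 7.058, which a liver array of the source does not account for. Of the arrays labelled primary tumour, 1 library did not match its group's labels and lay within the normal liver range.

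The arrays labelled HT29 and SW620 correlated at 0.9558 over 6198 genes, within the range of DLD-1 repeats (0.9045 to 0.9846) and above every other pair of colon lines (at most 0.8511). This is in line with 1 line on both arrays. HT29 and WiDr, a derivative of HT29, correlated at 0.7843, which argues against correct labels on both. Both HT29 and SW620 had VIM at 11.31 and 11.14 and KRT20 and CDX2 at the floor. Which label is wrong was not tested.

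Groups were redrawn in 100 splits with the real one among them, without the source block. The real split had the most genes, 1 of 100 splits, for primary tumours against mucosa (700, highest other 161), polyps against mucosa (748, 51), primary tumours against polyps (284, 0), liver metastases against primary tumours (180, 2), lung metastases against primary tumours (86, 1), liver against lung metastases (219, 0) and the lines against primary tumours (1568, 310). The same held for liver metastases against normal liver (2468, 1491) and lung metastases against normal lung (1587, 1124). No redrawn split reached the real count for these, and 100 splits cannot give less than 1 in 100. Arrays outside shared sources were exchanged singly, so the splits ignore that some were repeats of 1 source. For the polyps divided by disease label the count found was 0, so all 100 splits had at least as many (highest other 1) and the count of splits tells nothing.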
